A study of Canis lupus familiaris with 5 samples.

How the data were processed

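Gene expression was measured on Affymetrix canine arrays in total RNA of 5 canine lymphoid cell lines, 1 array per line, grown in RPMI with 10% FBS. Per the labels, RNA was extracted with Trizol, had a RIN above 9 and was labelled with biotin. Lymph node specimens named in the extraction protocol were not analysed here. The lineage label gave the groups: 17-71 and GL-1 as B-labelled (n = 2), CL-1, CLGL-90 and CLL-1390 as T-labelled (n = 3), with the LGL line CLGL-90 counted as T. No line had a replicate array, so every spread and p-value measures the variation between these lines only, and the number of arrays limits precision.

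The deposited values are log2 intensities per probe set. Background correction, normalization between arrays and summary were done by the authors with GCRMA, per the submitters' processing notes; its version, scanner settings and filters are not given in the sources used here. Array medians ran from 6.87 to 7.00, quantiles differed from the mean array by at most 0.19, and 15.3 to 17.3% of probe sets lay under log2 5. The 59 control probe sets for sequences absent from dogs had medians of 4.07 to 4.29 and maxima of 6.39 to 6.76, which served as a guide to background. A value above them need not show expression. The probe set of CD14, for example, read 7.95 to 8.26 in every line, which shows neither expression nor its absence. The table held 43035 probe sets; 111 Affymetrix controls were left out. Of the remaining 42924, 29254 had 1 gene symbol, 439 had several and were not used at gene level, and 13231 were not in the annotation. The gene IDs of 27680 annotated probe sets (94.6%) were found in the reference gene table of assembly UU_Cfam_GSD_1.0, which was used for names and neighbouring genes only.

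Probe sets reaching log2 5 on at least 2 arrays were tested (36661; 6263 dim ones were not). A gene was represented by its probe set of highest mean (15115 genes, 14164 tested). B-labelled and T-labelled lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior df 1.75, residual df 3), two-sided, with Benjamini-Hochberg adjustment at 0.05. The median difference over tested probe sets was -0.012, and over genes -0.027. Tested on simulated data, with 200 probe sets shifted on noise of the same size, the fit recovered 0% at log2 1 and 2, 70.5% at 4 with 4 false calls, and 85% at 6 with 8 false calls.

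For 29 gene lists, camera with a preset inter-gene correlation of 0.01 gave a two-sided p, adjusted over lists; members were also adjusted over the list alone. Tested on simulated data in which genes varied independently, a myeloid list shifted by log2 2 was recovered and 0 other lists were called. This cannot show how often lists are called falsely where members vary together (estimated correlation 0.10 in the myeloid list). The lists cover B lineage, T lineage, cytotoxic and natural killer, immature lymphoid and progenitor, plasma cell, germinal centre, MHC class II, MHC class I and antigen processing, myeloid, fibroblast, endothelial and epithelial, erythroid and megakaryocyte, mitosis and DNA replication genes. They also cover cell cycle brakes and tumour suppressors, apoptosis, NF-kB targets, interferon response, cytokine receptors and JAK-STAT, homing and adhesion, drug transport and response, MYC and ribosome biogenesis, glycolysis, hypoxia, unfolded protein and amino acid stress, heat shock and immediate early, Notch, histone and DNA methylation enzymes, and ribosomal proteins.

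Similarity was the Pearson correlation of each pair of arrays over tested probe sets, with an exact permutation over the 10 splits into 2 and 3 lines. Single lines were described without a test, by the gap between a gene's value and the nearest other line and by each list's median difference from the median of the other 4 lines. Its percentile was taken among 10000 random lists matched on mean expression. Genes were named by a rule: those past the threshold, filled up to 10 per direction by the lowest unadjusted p without overlap; up to 4 per list by absolute difference; per line, the 8 largest gaps above and the 5 largest below; and 32 fixed immunophenotype and tumour genes. Of these 32, 7 had no probe set of their own and are not reported.

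Groups, the tests of the comparisons, gene lists, the naming rule and the alternatives were chosen before the data were examined. Chosen after seeing the data were 1 alternative threshold (the highest non-dog control of each array), the 6 lists whose genes were recomputed under the alternatives, and the tests of patterns in the closing section other than the counts of probe sets and genes over splits. The alternatives were no filter, a filter at log2 7, quantile normalization again, centring on array medians, a floor of log2 4, an intensity trend with a robust prior, CLGL-90 as its own group, other summaries of a gene's probe sets, an estimated inter-gene correlation, fry, other similarity measures, other low thresholds (log2 4 and 6), the mean of the other 4 lines, and leaving out each line. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for profiles and figures.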

Results

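LYZ, the myeloid gene that encodes lysozyme, was higher in both B-labelled lines (17-71 and GL-1) than in the T-labelled lines (CL-1, CLGL-90 and CLL-1390). It stood at log2 12.20 ± 0.27 (mean ± SD, n = 2 lines) against 3.69 ± 0.38 (n = 3), a difference of 8.51 (SE 0.29, adjusted p = 0.0225) seen in 2 of 2 B-labelled lines. The T-labelled values of LYZ lay at background (non-dog control medians 4.07 to 4.29), so the size of the difference depends on the floor; its other probe set differed by 5.79. By 1 probe set, FCER1A, the alpha chain of the high-affinity IgE receptor, was higher by 6.35 (SE 0.28, adjusted p = 0.0440 over probe sets). In the test over genes FCER1A was represented by another probe set of higher mean and did not pass. FCER1A lies outside the rule for named genes and was chosen after its values were seen. In limma, 5 of 36661 probe sets passed, all higher in the B-labelled lines: 2 for LYZ, 1 for FCER1A and 2 without a gene name (differences 5.19 and 4.15). The T-labelled values of FCER1A (4.93 to 5.38) and of the 2 unnamed probe sets (5.16 to 5.81) lay under the highest non-dog controls (6.39 to 6.76). The sizes of their differences thus also depend on background. Among 14164 genes, LYZ alone passed. Over the alternatives the counts ran from 0 to 15 probe sets and from 0 to 11 genes; both were 0 in limma with CLGL-90 as its own group (1607 and 627 unadjusted) or without any 1 line (1186 to 2108 and 473 to 760 unadjusted). The counts at an unadjusted p under 0.05 were 1365 probe sets (808 higher in B-labelled lines, 557 higher in T-labelled lines) and 498 genes (268 and 230). The groups did not overlap in 2178 genes (15.4%; chance gives 20%).

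Further genes, several of them typical of granulocytes and macrophages, followed LYZ without passing the test over all genes. S100A9 and S100A8, the subunits of calprotectin, differed by 6.32 (SE 0.32) and 3.88 (SE 0.21); S100A4 differed by 6.36 (SE 0.38). SPI1, which encodes the transcription factor PU.1, differed by 3.81 (SE 0.23), AIF1 by 5.23 (SE 0.33), FCER1G, the signalling chain shared by Fc receptors, by 5.25 (SE 0.34), and RNLS by 4.23 (SE 0.25). Each of these 7 genes had an adjusted p of 0.0523. UPP1, uridine phosphorylase, differed by 3.82 (SE 0.26, adjusted p = 0.0569), and CXCL8, a chemokine that attracts neutrophils, by 2.40 (SE 0.17, adjusted p = 0.0682). In 7 of the 10 genes, LYZ included (LYZ, S100A9, S100A8, RNLS, SPI1, FCER1G and CXCL8) every T-labelled value lay at or under the highest non-dog control of its array (S100A9 at 4.28 to 4.55, S100A8 at 4.52 to 4.98), and in AIF1 2 of 3 did, so the sizes of these differences depend on background. CXCL8 lay at or under the highest non-dog control on every array (6.30 and 6.24 in the B-labelled lines), so its difference cannot be told from background. The myeloid list was called higher in the B-labelled lines with the preset correlation (mean difference 2.12, median 1.03, 19 genes, camera FDR 1.31e-15) and by fry (0.0339), and not with an estimated correlation (0.346). Of the 19 genes, 8 were higher in both B-labelled lines than in every T-labelled line (chance gives 10%), 1 passed over all genes and 6 when adjusted over the list alone (LYZ, S100A9, S100A8, AIF1, SPI1 and CYBB, a subunit of the phagocyte oxidase). Among surface markers of the list, FCGR1A stood at 7.72 in 17-71 and 11.10 in GL-1 against 6.09 to 6.46 (difference 3.07, SE 1.02, not past the threshold), and TREM1 at 8.66 in GL-1 against 6.01 to 6.33 in the other 4 lines. CD14 (7.95 to 8.26 over the 5 lines) and ITGAM (6.47 to 7.65) varied by 1.17 or less, and no line shows that their probe sets respond. LYZ lost its call when CLGL-90 was its own group (adjusted p = 0.236), and without CL-1 (0.181), CLGL-90 (0.232) or CLL-1390 (0.127); the range over 12 alternatives was 0.00356 to 0.236. Without 17-71 or without GL-1, LYZ reached log2 5 on 1 array and was not tested.

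**Figure D1:**
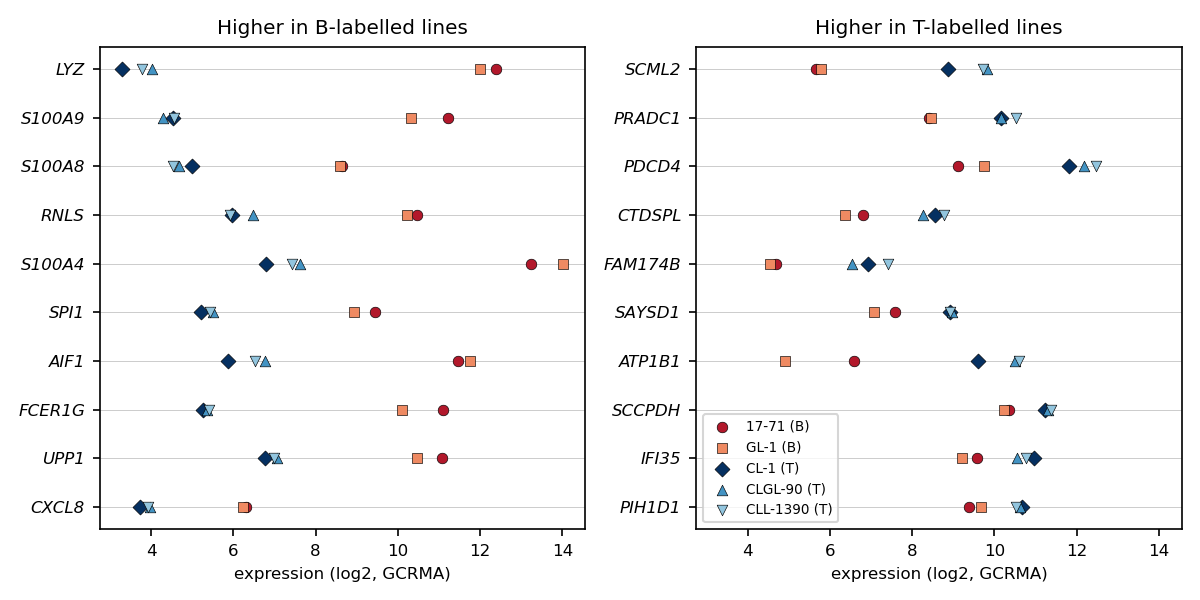
Expression in each line of the 10 genes named as higher in the B-labelled lines and the 10 named as higher in the T-labelled lines (log2, 1 array per line). Only LYZ passed the test over genes (difference 8.51, adjusted p = 0.0225).

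NF-kB targets and cytokine receptors were the other lists called higher in the B-labelled lines, 3 lists in all, where the other 9 splits of the lines into 2 and 3 called 1 to 8. NF-kB targets differed by 0.50 on average (median 0.30, 21 genes, FDR 0.000958; adjusted p = 0.768 with an estimated correlation, and 0.765 by fry), and 15 of the 21 were higher. ICAM1, an adhesion molecule, stood at 10.28 in 17-71 and 7.54 in GL-1 against 6.09 to 6.77 in the T-labelled lines, a difference of 2.39 (SE 0.85). REL, an NF-kB subunit, differed by 1.99 (SE 0.93), whereas CCL3, a chemokine, differed by -2.23 (SE 2.03) and lay at 13.29 in CLGL-90. No NF-kB target passed over all genes, and 2 passed adjusted over the list alone (CXCL8 and EBI3). Cytokine receptors and JAK-STAT genes differed by 0.48 on average (median 0.20, 31 genes, FDR 0.00731; adjusted p = 0.768 with an estimated correlation, and 0.901 by fry), and 0 of 31 passed by limma over all genes or adjusted over the list alone. IL1R2, the decoy receptor of interleukin 1, differed by 4.03 (SE 1.40), IL7R by 2.41 (SE 0.57) and IFNGR1 by 2.02 (SE 1.26). IL1R2 stood at 11.73 in 17-71 and 7.11 in GL-1. All 3 T-labelled values of IL1R2, and 2 of 3 for IL7R, ICAM1 and REL, lay at or under the highest non-dog control of their array. The sizes of the differences of these 4 genes thus depend on background. Without 17-71 the NF-kB mean was -0.03 (FDR 0.593; range over 15 alternatives 0.000106 to 0.768) and that of cytokine receptors 0.27 (0.388). Without CL-1, cytokine receptors stood at 0.30 (0.175; range over 15 alternatives 0.000157 to 0.901), and at the stricter filter of log2 7 at 0.61 (0.0802).

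T-lineage genes were on average lower in the B-labelled lines without passing (mean -1.12, median -0.83, 23 genes, FDR 0.0851), with 18 of 23 lower. SH2D1A, a signalling adaptor of T and natural killer cells, differed by -4.36 (SE 2.14), CTLA4 by -3.94 (SE 2.26), CD247, the zeta chain of the T-cell receptor complex, by -3.69 (SE 1.497), and LCK, its proximal kinase, by -2.58 (SE 1.78). Both B-labelled values of SH2D1A, CTLA4 and CD247 lay in the range of the non-dog controls, so the sizes of these differences depend on background. Lines of 1 label differed among themselves: LCK lay at 10.65 in GL-1, and SH2D1A and CTLA4 lay at 4.24 and 4.91 in CLL-1390. The list passed without CL-1 (-1.57, FDR 0.00687), GL-1 (-1.59, 0.0460) or CLL-1390 (-1.42, 0.00240); its FDR over 15 alternatives ran from 0.00240 to 0.901. The genes with the lowest unadjusted p among those higher in the T-labelled lines were SCML2 (-3.75, adjusted p = 0.166), PRADC1 (-1.85, 0.249), PDCD4 (-2.73, 0.346), CTDSPL (-1.95) and FAM174B (-2.34, both 0.448). SAYSD1 (-1.61) and ATP1B1, a subunit of the sodium pump (-4.48), followed at 0.485, and SCCPDH (-0.995), IFI35 (-1.36) and PIH1D1 (-1.08) at 0.797. None of these 10 passed, and the B-labelled values of SCML2, FAM174B and ATP1B1 lay in the range of the non-dog controls.

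B-lineage genes did not separate the groups (mean 0.44, median 0.05, 19 genes, FDR 0.229). BTK, the kinase downstream of the B-cell receptor, differed by 4.88 (SE 2.38) and lay at 11.52 in 17-71, 11.46 in GL-1 and 11.23 in CLL-1390, against 3.93 in CL-1 and 4.68 in CLGL-90. CD40 (1.80, SE 1.302) and BANK1 (1.61, SE 1.24) were high in 17-71 alone, at 9.17 and 8.95, and CD79A (1.15, SE 0.73), a chain of the B-cell receptor complex, in GL-1 alone at 7.83. Every T-labelled value of CD40, BANK1 and CD79A lay at or under the highest non-dog control of its array, so these sizes depend on background. Probe sets for MS4A1 (5.71 to 6.79) and PAX5 (6.83 to 7.18) hardly varied over the 5 lines, and so cannot show whether these genes were expressed. Of the 20 B-lineage genes on the array, 6 reached log2 8 in a line and varied by log2 2 or more, so the list result rests on few responsive probe sets. Among these 6, BTK, CD40 and BANK1 were highest in 17-71. BCL11A (11.05) and CXCR5 (9.81) were highest in CL-1 and BLNK (9.90) in CLGL-90, both T-labelled lines.

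Among the other 24 lists none passed on the deposited values with all 5 lines. Cytotoxic and natural killer genes had a mean of -0.22 (FDR 0.872), and FCER1G passed adjusted over the list alone. TYROBP, the partner chain of many activating receptors, differed by 4.14 (SE 1.16), IL2RB by -2.87 (SE 1.16) and KLRG1 by -2.36 (SE 1.42). With CLGL-90 as its own group the cytotoxic list turned to 0.60 (FDR 0.0106; range over 15 alternatives 0.0106 to 0.985), and without CLGL-90 to 0.62 (0.0155). Means above 0 were found for MHC class II (0.63, FDR 0.287), apoptosis (0.57, 0.229; FAS passed adjusted over the list alone), immature lymphoid and progenitor genes (0.56, 0.0777) and drug transport (0.43, 0.0659). Drug transport passed after quantile normalization again (0.44, 0.0327) and with centred arrays (0.40, 0.0324; range over 15 alternatives 0.00114 to 0.901), and the progenitor list with centred arrays (0.53, 0.0490; range 0.000598 to 0.985). Means above 0 were also found for germinal centre (0.28, 0.302), heat shock (0.21, 0.809), histone and DNA methylation enzymes (0.18, 0.0887) and the interferon response (0.15, 0.554). In the interferon list OAS2 and IFI35 passed adjusted over the list alone, in opposite directions. MHC class I (0.13, 0.302), unfolded protein stress (0.06, 0.759) and plasma cell genes (0.05, 0.960) lay near 0. Means below 0 were found for fibroblast (-0.56, 0.482), hypoxia (-0.36, 0.287), glycolysis (-0.34, 0.152) and cell cycle brakes (-0.12, 0.403). Erythroid and megakaryocyte (-0.10, 0.818), DNA replication (-0.07, 0.759), Notch (-0.04, 0.715) and ribosomal protein genes (-0.03, 0.809) were close to 0. Mean and median differed in sign for homing and adhesion (0.25 and -0.21, FDR 0.748), mitosis (0.05 and -0.08, 0.809) and MYC and ribosome biogenesis (-0.01 and 0.03, 0.809). For MYC genes and for endothelial and epithelial genes (-0.17, 0.996) the camera test pointed up while the mean was negative.

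The labelled lineage did not order the lines by their expression as a whole. GL-1 (B) and CLL-1390 (T) were the most alike of the 10 pairs (Pearson r = 0.921 over 36661 probe sets), followed by 17-71 and GL-1 (0.912) and by CLGL-90 and CLL-1390 (0.899). CL-1 stood furthest from the others (mean r = 0.881), and its pair with CLL-1390, also T-labelled, was the lowest (0.876). The mean correlation was 0.892 within lineages and 0.895 between them, a difference of -0.0026 (exact one-sided p = 0.7, smallest possible 0.1). The sign of this difference turned over the 1000 probe sets of highest variance (0.0088), and without CL-1 (0.0057), CLGL-90 (0.00082) or CLL-1390 (0.0058).

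**Figure D2:**
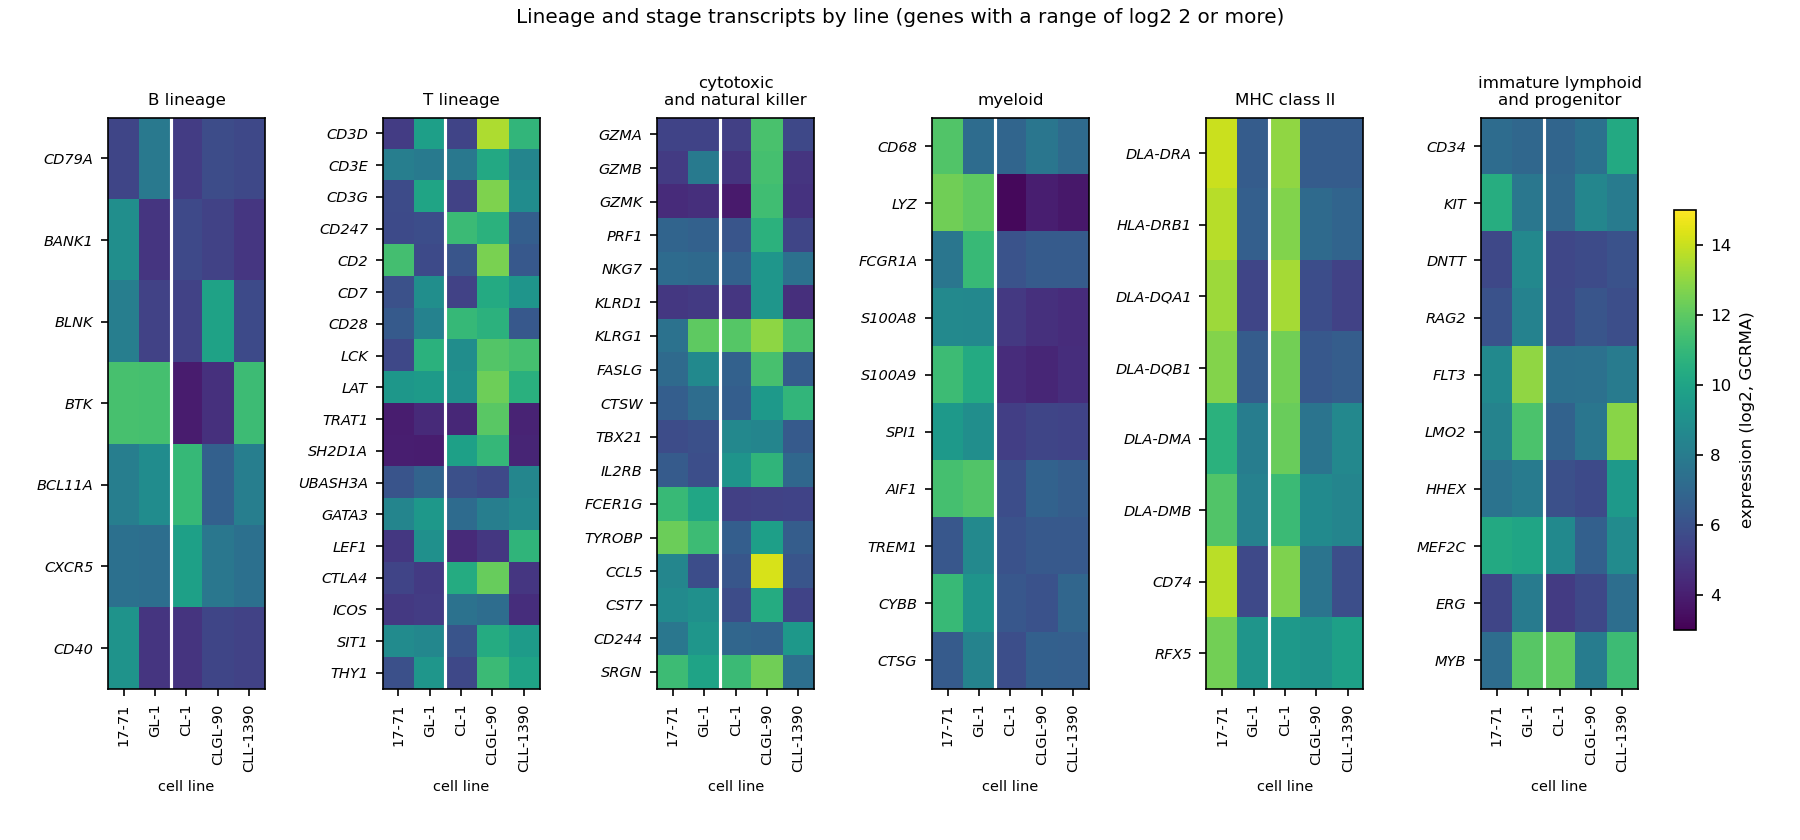
Expression of lineage and stage transcripts in each line (log2, 1 array per line), for genes of 6 lists whose range over the lines was 2 or more; the white line parts B-labelled from T-labelled lines. DLA-DRA stood at 14.05 in 17-71 and 13.005 in CL-1, and CD3D at 13.51 in CLGL-90, 10.89 in CLL-1390 and 9.78 in GL-1.

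MHC class II transcripts, which serve antigen presentation to helper T cells, were abundant in 17-71 and CL-1 and low in the other 3 lines. DLA-DRA stood at 14.05 and 13.005 against 6.47 to 6.51, CD74, the invariant chain, at 13.74 and 12.67 against 5.66 to 7.62, and DLA-DQA1 at 13.23 and 13.41 against 5.36 to 5.84. The list median lay 3.11 above the other lines in 17-71 and 2.57 above in CL-1, and at -1.54 in GL-1. RFX5, a factor that binds class II promoters, stood at 12.45 in 17-71 against 9.19 to 9.83. CIITA, the class II transactivator, varied little (9.20 to 9.76), and no line shows that its probe set responds. Each line is 1 array with no replicate, so neither a p nor an SD is given for single lines. In 30 of the 40 named gaps above and 20 of the 25 below, the lower value was at or under the highest non-dog control (6.39 to 6.76), so those sizes and their order depend on background.

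Line 17-71, labelled as a B-lymphoid malignancy, combined myeloid and activation transcripts with little T-lineage expression. The NF-kB list lay 0.62 and the myeloid list 0.40 above the other lines, and the T-lineage list at -0.70. BIRC3, an inhibitor of apoptosis, stood at 13.25, CCR6, a chemokine receptor, at 11.13, KIT, the stem cell factor receptor, at 10.46, and CD38 at 9.06. CD2, an adhesion receptor of T cells, reached 11.42. The largest gaps above the nearest other line were those of FZD6, a Wnt receptor (6.75), HORMAD1, a meiotic protein (6.67), TASL (5.58), CCDC179 (5.26), ETV1, an ETS transcription factor (5.20), LOC478001 (5.14), DLA-79 (5.03) and CAPN2 (4.94). The largest gaps below were those of YBX3 (6.81), YTHDF3 (6.501), PGM2 (6.34), GSTO1 (6.30) and MAGED2 (4.23). The other probe sets of CCDC179 and YTHDF3 did not show the gap.

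CL-1, labelled as a T-cell line, was low in most T-lineage transcripts and high in a few. The T-lineage list lay at -0.49 from the other lines, and 12 of 17 varying T-lineage genes were within log2 1 of their lowest value, CD7 (5.38), LEF1 (4.45) and TRAT1 (4.32) among them. CD247 stood at 11.16, CD28 at 11.06, CTLA4 at 10.40 and SH2D1A at 9.80, while CD3D (5.44) and CD3G (5.34) were as low as in 17-71. LCP2 and SLA, adaptors of antigen receptor signalling, lay 6.09 and 5.92 below every other line, beside CDKN2AIPNL (7.09), HEBP1 (6.85) and MVP, the major vault protein (6.18). MSX2, a homeobox factor (7.09), SDC2 (6.59), CCR8, a chemokine receptor of regulatory and skin-homing T cells (6.46), UCHL1 (6.07) and BMP2 (5.84) had the largest gaps above. TFAP2B (5.83), RUBCNL (5.51) and CHRNA9 (5.29) followed. CL-1 had the most genes at least log2 2 apart from every other line, 145 above and 56 below, against 51 and 21 in GL-1.

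GL-1, labelled B-cell, held early lymphoid, T-lineage and myeloid transcripts side by side. The progenitor list lay 0.66 above the other lines: FLT3, a receptor of early progenitors, stood at 13.0002, LMO2 at 11.60, DNTT, which adds nucleotides at antigen receptor joints, at 8.59, and RAG2, a subunit of the recombinase, at 8.31. CD3D (9.78), CD3G (10.01), LCK (10.65), CD7 (8.92) and LEF1 (9.00) were above 17-71 and CL-1, whereas CD2 (5.71), CD247 (5.85), CTLA4 (5.02) and SH2D1A (3.94) were low. The more variable probe set of CD3E read 6.18 in GL-1, near 17-71 (5.92) and CL-1 (5.53). It lay under the highest non-dog control of GL-1 (6.66). The T-lineage list lay at -0.06, and 7 of 17 varying T-lineage genes were within log2 1 of their lowest value. CD79A (7.83) and EBF1, an early B-cell factor (7.71 against 6.23 to 6.41), were highest in GL-1. The myeloid list lay 1.17 above the other lines, with FCGR1A at 11.10. The largest gaps above were those of AMBN (5.61), IL22RA2 (5.41), RGS18 (5.0045), P2RY13 (4.88), SUCNR1 (4.73), S100A6 (4.49), N4BP2L1 (4.42) and FLT3 (4.33); the other probe set of IL22RA2 did not show its gap. Below every other line lay SHCBP1 (7.03), CTH (6.20), ASAH1 (5.37), PBDC1 (5.05) and DGUOK, a mitochondrial nucleoside kinase (4.81).

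CLGL-90, labelled as an LGL T-cell line, had the transcripts of a cytotoxic T cell. The T-lineage list lay 2.23 and the cytotoxic list 1.81 above the other lines. CD3D stood at 13.51, CD3G at 12.69, CCL5 at 14.29, and GZMA, GZMB and GZMK, serine proteases of cytotoxic granules, at 11.54, 11.48 and 11.30, with PRF1, perforin, at 10.72. The largest gaps above were those of DPP4, the surface peptidase CD26 (7.97), LOC475935 (7.70), HAPLN1 (7.67), TRAT1, a T-cell receptor adaptor (7.48), KCNIP4 (7.30), GZMK (6.57), BRINP3 (6.19) and GZMA (5.94). CTPS2 (5.38), PECR (5.03), UBE2E3 (4.33), RNASET2 (4.18) and TCF4 (3.99) had the largest gaps below; the other probe set of GZMK did not show its gap. ABCB1, the drug efflux pump P-glycoprotein, reached 8.96 against 3.96 to 4.54, and ASNS, asparagine synthetase, stood at 6.45 against 10.39 to 13.48. The hypoxia list lay 0.71 above the other lines.

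CLL-1390, labelled as a T-cell line, paired some T-lineage with some progenitor transcripts. CD3D (10.89), LCK (11.44), CD7 (9.25), THY1 (9.98) and LEF1, a transcription factor of early T cells (10.83), stood beside CD34, a marker of progenitors (10.27 against 6.89 to 7.41), LMO2 (12.87) and HHEX (9.51). CD2 (6.30), CD28 (6.32), CD247 (6.58), CTLA4 (4.91) and SH2D1A (4.24) were low, and 7 of 17 varying T-lineage genes were within log2 1 of their lowest value. So were 4 of 9 varying progenitor genes: KIT (7.99), FLT3 (7.98), DNTT (6.04) and RAG2 (5.87). The T-lineage list lay 0.45 and the progenitor list 0.27 above the other lines, and the cytotoxic list at -0.38. The largest gaps above were those of F13A1, a coagulation factor subunit (7.19), MMRN1 (7.05), CD36 (6.25), PIPOX (5.15), ESAM (5.10), TSPAN33 (4.43), TMLHE (4.08) and GPR37 (4.03). ANXA1 (6.80), GPR65 (5.38), CCND2, a cyclin (5.21), VIM, vimentin (4.91) and GCAT (4.26) had the largest gaps below.

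**Figure D3:**
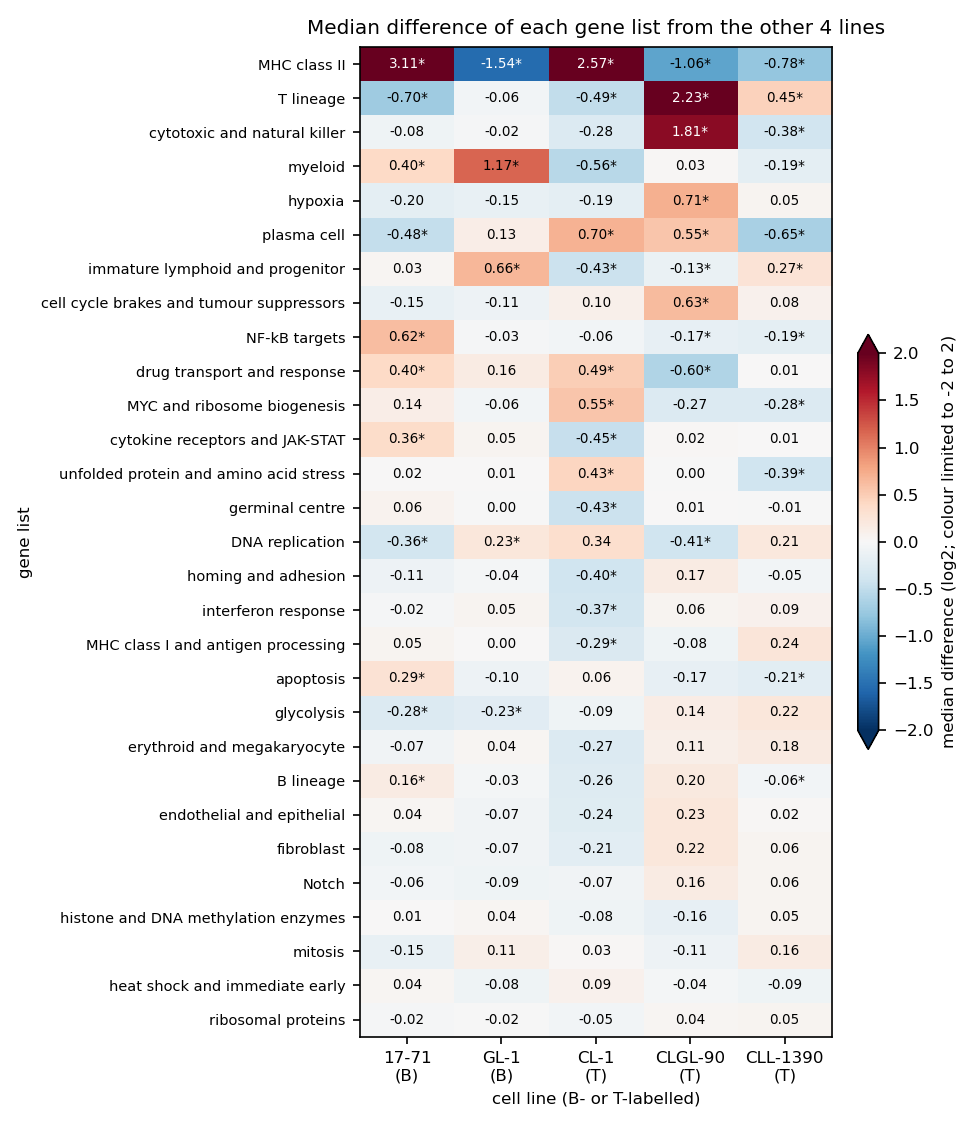
Median difference of each of 29 gene lists from the median of the other 4 lines (log2); an asterisk marks medians within the outer 2.5% at either end of 10000 random lists matched on mean expression. The MHC class II list ran from 3.11 in 17-71 to -1.54 in GL-1.

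Of the 145 list medians, 50 lay within these outer ranges, against 7.25 by chance; members of a list vary together, so the random lists measure rank and give no test.

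Of 32 immunophenotype and tumour genes fixed beforehand, 25 had a probe set of their own. CD4 (8.10 to 8.43), CD5 (7.52 to 8.04), CDKN2B (5.04 to 5.43) and B2M, the light chain of MHC class I (13.90 to 14.41), varied little over the 5 lines. For CD4, CD5 and CDKN2B no line shows that the probe set responds, so even values do not show even expression. CD3E stood at 10.24 in CLGL-90 against 7.81 to 8.48; its other probe set, which varied more, read 12.80 in CLGL-90, 8.58 in CLL-1390 and 5.53 to 6.18 in the rest. CD8A stood at 7.89 in CLGL-90 against 6.29 to 6.49. IL2RA was highest in 17-71 (8.35 against 5.93 to 6.92), BCL2 in GL-1 (9.44 against 8.27 to 8.69), and the glucocorticoid receptor gene NR3C1 in CL-1 (10.70 against 8.63 to 9.66). RB1, the retinoblastoma suppressor, stood at 9.87 in CLGL-90 and 5.50 in CL-1, and MTAP, which neighbours CDKN2A in mammals, at 7.83 in CLGL-90 against 9.62 to 11.95. MYC lay between 10.05 and 11.17, and PTPRC, the leukocyte antigen CD45, between 8.88 and 11.11. A low value can be a weak probe set: control probe sets for sequences absent from dogs reached 6.39 to 6.76.

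RNA integrity was alike over the arrays. The difference between 3' and 5' control probe sets ran from -0.065 to 0.023 for GAPDH and from -0.55 to -0.26 for actin, and neither split the lines by lineage.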

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

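The alternative that takes the highest non-dog control of each array as the low threshold was chosen after seeing the data; all others were planned. No paired analysis was possible because the lines are different cell lines and their numbers carry no pairing. Of 435 list means under alternatives, 408 kept their direction, as did 513 of 517 differences of named genes; the latter cover 38 genes, those of the lineage comparison and of 6 lists chosen for this after their values were seen, and other list genes have no such values. Of the 50 list medians of single lines at the outer ends of random lists, 50 moved by less than 1 SD of those lists with a floor of log2 4, 33 with the mean of all probe sets and 25 against the mean of the other 4 lines; of 65 gaps, 42 moved by log2 1 or less with the mean of all probe sets. Probe sets past the threshold numbered 3 without a filter, 14 at a filter of log2 7 (fewer tested), 3 with centred arrays, 15 with an intensity trend and robust prior, and 0 in limma with CLGL-90 as its own group (1607 unadjusted). Genes numbered 9 at log2 7, 8 after quantile normalization again, 10 with the trend and robust prior, 11 with the probe set of highest variance, and 0 in limma with CLGL-90 as its own group (627 unadjusted). S100A9, S100A8, RNLS, S100A4, SPI1 and AIF1 passed in 4 alternatives each. List calls numbered 5 with centred arrays, 5 with CLGL-90 as its own group, 0 by camera with an estimated correlation (1 unadjusted) and 1 by fry; the myeloid list kept its mean of 2.12 but not its call with an estimated correlation. At log2 7 the plasma cell (-0.15), MYC (0.015) and Notch (0.015) means reversed; with CLGL-90 as its own group the cytotoxic (0.60), cell cycle brakes (0.042) and unfolded protein (-0.044) means did; with the mean of all probe sets those of MHC class I (-0.054) and MYC (0.0058). The similarity difference reversed to 0.0088 over the 1000 most variable probe sets. CLL-1390 had 14 fixed genes above the highest non-dog control, against 23 at log2 5. The cause of these changes was not tested, beyond the fewer probe sets or lines used.

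Leaving out each line in turn, with an arm of 1 line assumed to vary like the others, gave 0 probe sets and 0 genes past the threshold every time by limma (1186 to 2108 and 473 to 760 unadjusted), and 2 to 9 list calls: 2 without 17-71, 9 without CL-1, 6 without GL-1, 5 without CLGL-90 and 6 without CLL-1390. Ranges were -0.017 to 0.0058 for the similarity difference, -0.35 to 3.95 for CD40, -0.43 to 3.65 for BANK1, -0.016 to 2.31 for CD79A and -0.21 to 2.86 for BCL6. List means ran from -1.59 to -0.40 (T lineage), -0.65 to 0.62 (cytotoxic), -0.29 to 0.19 (plasma cell), -1.09 to 2.35 (MHC class II), -0.037 to 0.30 (MHC class I), -0.41 to 0.026 (endothelial and epithelial) and -0.25 to 0.058 (erythroid). They ran from -0.037 to 0.14 (mitosis), -0.30 to 0.11 (DNA replication), -0.28 to 0.015 (cell cycle brakes), -0.029 to 0.80 (NF-kB), -0.15 to 0.22 (MYC), -0.044 to 0.24 (unfolded protein), -0.15 to 0.56 (heat shock) and -0.10 to 0.041 (Notch). Without CL-1 the MHC class II (1.64), fibroblast (-0.46), apoptosis (0.64), drug transport (0.52), MYC (0.22) and unfolded protein (0.24) lists passed; without GL-1 MHC class II (2.35) and apoptosis (1.01); without CLGL-90 DNA replication (-0.30); without CLL-1390 hypoxia (-0.49) and progenitor genes (0.96), the latter also without 17-71 (1.06). Signal over background limits low values: probe sets near the non-dog maxima of 6.39 to 6.76 cannot be told from background.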

Other observations

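All tests of the patterns below were chosen after the result was seen, except the counts of probe sets and genes over other splits of the lines. Beyond the comparisons above, neighbouring genes stood out together in 4 of 10 tests of single lines, above or below; the other 6 did not pass (lowest adjusted p = 0.173). In GL-1 the purinergic receptor genes P2RY14 (10.70), P2RY13 (10.59) and P2RY12 (8.51), which lie side by side, were each at least log2 2 above every other line. Pairs were counted within 3 steps in gene order, so genes in a row give several pairs that are not separate places. Random placement also ignores gene families. Several pairs join members of 1 family, so an excess over random placement has no single reading. GL-1 had 4 pairs against 0.50 under random placement (adjusted p = 0.011). All but the pair of PAN3 and FLT3 came from these receptor genes. CLGL-90 had 6 pairs against 1.71 (adjusted p = 0.0162), among them the chemokine genes CCL4 and CCL3 (8.61 and 13.29) and CCL16 and CCL5 (7.30 and 14.29). CLL-1390 had 5 pairs against 0.64 (adjusted p = 0.009), with GPRASP1 (8.87), ARMCX5 (8.54) and GPRASP2 (9.45) in a row. CL-1 was lower than every other line in both metallothionein genes MT1E (4.82) and MT2A (4.80), among 4 low pairs against 0.61 (adjusted p = 0.0162); the other 3 lie among BRD7, TENT4B and HEATR3, part of the run described below.

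Some matrix and homing genes, picked after their values were seen from lists that did not pass, stood high in 1 or 2 lines. FN1, fibronectin, stood at 14.01 in CL-1 and 11.002 in CLL-1390 against 4.66 to 7.24, and SPARC, a matrix glycoprotein, at 11.02 in CLGL-90 and 10.24 in CLL-1390 against 5.88 to 6.86. CCR9, a receptor that guides cells to thymus and gut, was shared by GL-1 (11.50) and CLL-1390 (11.16) against 6.4995 to 6.93. CXCR6 stood at 10.36 in CLGL-90 against 4.79 to 5.50.

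Of the 10 splits of the 5 lines into 2 and 3, 4, the labelled split included, gave as many probe sets as the labels (real value 5, highest other 20) and 4 as many genes (real value 1, highest other 8); 9 gave as many list calls (real value 3, highest other 8). With 10 splits a share under 0.05 is impossible. The splits that joined 17-71 with CL-1 (20 probe sets, 8 genes) and CL-1 with CLGL-90 (19 and 3) called several times the real counts. So did GL-1 with CLL-1390 for genes (9 and 6), while the remaining unlabelled splits called 0 probe sets and 0 genes. The higher counts may reflect a structure of the samples, which was not tested. The median difference over probe sets was -0.012, a value that the normalization itself fixes and that decides nothing about scaling.

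Of 19 myeloid genes, 8 were higher in both B-labelled lines than in every T-labelled line and 1 passed over all genes; the list lost its call with an estimated correlation (0.346). Against cross-hybridisation of single probe sets, 100% of the other annotated probe sets of the same genes (3 of 3, for LYZ and CYBB) were at least log2 1 higher. The remaining 4 of the 6 genes have no further annotated probe set, which leaves this open for them. Myeloid cells mixed into both cultures cannot be told apart from expression by the cells of the lines themselves. Only 2 of 10 surface markers had probe sets that varied by log2 2, FCGR1A and TREM1 (median difference 2.15). TREM1 was high in GL-1 alone, and these 2 were added after their values were seen. Outside these 10, CD68 of the myeloid list stood at 11.76 in 17-71 against 6.91 to 7.73 in the other lines (7.22 in GL-1). ITGAX of the homing list stood at 8.80 in 17-71 against 5.76 to 6.74. CD68 and ITGAX were picked by their values. For GL-1, cells carrying MHC class II are argued against by 8 class II genes, which lay in GL-1 at a median of -0.17 (highest 0.072) from CLGL-90 and CLL-1390, where class II is low, while the 6 myeloid genes lay 4.55 above; this test was chosen when those values were known. In 17-71, where DLA-DRA stood at 14.05, this value excludes nothing. Expression of myeloid genes by the cells of both lines themselves stays an untested hypothesis, and the lineage of both was taken from the labels.

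T-lineage transcripts were found in GL-1, labelled B-cell. RNA of CLL-1390 mixed into GL-1 would bring all its abundant transcripts, but 5 of 13 genes bright in CLL-1390 and dim in the 3 lines other than GL-1 (F13A1, MMRN1, CD36, ESAM and TSPAN33) lay in GL-1 over log2 2 further below it than any T-lineage transcript (largest shortfall 1.83). A test run earlier came out the other way: the lower quartile of the 13 shortfalls was 0.54, under the median of 0.74 for T-lineage transcripts; it was replaced after the genes were viewed. The same count for CLGL-90 was 9 of 25, with a lower quartile of 4.004. The other 8 genes, CA2, CCR9 and DACH1 among them, lay within 1.95 of CLL-1390, so a programme shared by both lines, or a label that does not describe GL-1 fully, may explain the transcripts; neither was tested.

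A run of 6 neighbouring expressed genes was low in CL-1: AKTIP (6.53), RBL2 (4.33), CYLD (5.48), BRD7 (6.90), TENT4B (6.84) and HEATR3 (4.94), each at least log2 1 below every other line, with FTO (8.37 against 7.86 to 8.68) beyond AKTIP; beyond HEATR3 the edge was less sharp, with N4BP1 at 7.93 against 8.55 to 8.97 and LONP2 at 10.25 against 10.30 to 11.87. The longest run under shuffled gene order was 4 (adjusted p = 0.005), in a test chosen after the genes had been seen; shorter runs of 3 also passed in GL-1 (0.01) and CLGL-90 (0.04). Failure of single probe sets is argued against for 4 of the 6 genes by their other probe sets at 7 or more in the other lines, of which 100% (6 of 6, the least by 0.74) were at least log2 0.5 below every other line; for the remaining 2, CYLD and BRD7, it stays open. Loss or silencing of a chromosome segment could produce such a run, but expression does not separate the 2, and no DNA was analysed here. By the values above, 3 of the 6 genes (AKTIP, BRD7 and TENT4B) stayed above the highest non-dog control of CL-1 (6.39). Further probe sets of AKTIP (4.68) and TENT4B (5.45) lay under it in CL-1, so this count depends on the probe set chosen. BRD7 had no further probe set at 7 or more in the other lines. Loss or silencing stays a hypothesis, found and tested on the same data.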
